A study of Drosophila melanogaster with 12 samples.

How the data were processed

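Poly(A) RNA of wing imaginal discs of Drosophila melanogaster larvae in the third instar was sequenced from 12 libraries, made with an Illumina TruSeq kit per the labels. Regenerating discs and undamaged control discs were each collected at 0 h, 15 h and 25 h, with 2 libraries of 40 discs in each of the 6 groups. The labels call regenerating and control discs separate genotypes and do not describe them further. Grouping followed the sample titles.

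The values are FPKM, fragments scaled to transcript length and to the size of the library, that the authors deposited, 1 column per group merged over the replicates, for 17158 FlyBase gene identifiers. The submitters' processing notes name STAR 2.4.0j, RSEM and the genome build dm6, without saying which step each served. How the replicates were merged is not given in the sources used here. Each value is printed as the authors' merged value, so no spread between replicates, and no test or p-value within a time, could be computed, and no difference has a replicate check. No test over the 3 times jointly was run. The table holds FPKM without counts, so read depth is unknown. 1 further column of values with no sample of this series was not used.

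In 5 of the 6 columns decimal points had been lost. Every whole number of at least 1000 in these columns, 19569 in all, ended in 5 except 3, while no value of 1 or more carried 3 decimals. The 19565 values concerned, between 41.8% and 48.4% of the values above 0 of a column, were divided by 1000. The 3 others were kept, and 1 value, Act5C in regenerating discs at 25 h, could be read either way and was set aside. The control column at 0 h has at most 2 decimals and no lost points, so whether it is a rounded mean or 1 library is unclear, which bears on every ratio at 0 h and every change from 0 h in control discs. This reading was made from the values, so every restored value rests on it. After it, Spearman rho between columns lay between 0.948 and 0.981 over 8619 genes, across genes, which are not independent replicates.

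Gene symbols were paired with 16912 of the identifiers and 246 were not paired. Coordinates come from the Ensembl annotation of BDGP6.54, the same assembly as dm6. Some members of the lists, such as wg, matched no symbol and are not analysed here. Genes that share near-identical copies, overlap or lie antisense to another gene are uncertain, because how reads were assigned is not given in the sources used here.

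The design fixed before the data were examined used limma on replicate columns and, for 1 merged column per group, a rule of size. The second applied. A gene counted as higher or lower where log2 of (FPKM + 1) over (FPKM + 1) was at least 1 in size, with FPKM of at least 1 in 1 or both columns. A fold on this scale understates the change of low genes. Sets at 2 times were compared with the overlap of independent sets of their size. For each of 31 gene lists, also fixed before the data were examined, the members measured, higher and lower were counted. The median log2 ratio was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Groups of mitochondrial, nuclear respiratory chain and nuclear non-coding RNA genes were added later.

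Genes were named by a rule fixed beforehand. It took the 10 highest and 10 lowest log2 ratios of each comparison of regenerating with control discs, among genes of at least 5 FPKM in 1 or both columns, and the 5 highest and 5 lowest of each comparison of times. It added up to 4 members of each list with the largest change, 10 fixed genes, of which 9 were matched, and up to 15 genes past the rule at all 3 times. Of the 217 genes so named only a part is printed.

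Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median-of-ratios scaling, columns scaled to 1000000, and rules of 1.5 and 4 times. Added after the data were seen were restrictions to genes above 0 in both columns, alone and with median-of-ratios scaling, to genes with no restored decimal point and to nuclear protein-coding genes. Median-of-ratios factors were 0.715, 0.932 and 1.063 for control discs and 1.037, 1.228 and 1.102 for regenerating discs in order of time. They moved log2 ratios of regenerating over control by 0.54 at 0 h, 0.40 at 15 h and 0.05 at 25 h.

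The calculations were tested on simulated data for the comparison at 15 h. Over 17158 genes, 100.0% of values were recovered from simulated text with lost points. That recovery does not test whether the reading of lost points holds for the deposited values. Of 100 genes changed 2.5 times 90.0% passed the rule in the true direction and of 100 changed 4 times 100.0%, with 0.0 of 7650 unchanged genes past it. The changed genes were drawn from those of at least 5 FPKM in control discs. The simulated noise was small, so an unchanged gene could hardly pass the rule, and no further listing at 0 was simulated. These numbers therefore check the calculation and do not give the errors of the rule on the deposited values. Among 7850 genes, random lists of 20 genes had a mean percentile of 49.1, and a list shifted by 0.5 had a percentile of 100.0. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.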

Results

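RNA from wing imaginal discs of Drosophila melanogaster larvae in the third instar, the epithelial sacs from which the adult wings form, was sequenced after poly(A) RNA had been taken. Discs in which apoptosis had been induced and which then regenerated were compared with undamaged discs at 0 h, 15 h and 25 h after induction. Each of the 6 groups held 2 libraries of 40 discs. The deposited table gives 1 merged FPKM per gene and group for 17158 genes, so no spread between replicates could be computed and no difference below has a replicate check. The column of control discs at 0 h has fewer decimals than the other 5, and whether it is a rounded mean or 1 library is unclear, which bears on every ratio at 0 h and every change from 0 h in control discs. FPKM summed over all genes to between 1247527 in regenerating discs at 15 h and 1504200 in control discs at 0 h. Read depth is unknown. Genes were called higher or lower by a fixed rule of size, a log2 ratio of (FPKM + 1) of at least 1 in either direction with at least 1 FPKM in 1 or both columns. All ratios below are regenerating over control on that scale, which understates the change of low genes.

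Between 7465 and 9462 of the genes were listed at 0 per group. A value of 0 is not read as absence, because genes expressed in the other columns were also at 0 in control discs at 25 h, among them mt:ATPase8 of the mitochondrial genome at 204 FPKM in control discs at 15 h. Of genes with a median of 1 to 2 FPKM in the other columns, 46.8% were listed at 0 in control discs at 25 h, against 3.1% to 11.2% in the other 5 columns. The ratio of the median measured gene was itself above 0, at 0.47 at 0 h, 0.35 at 15 h and 0.10 at 25 h. Medians of gene lists are therefore given relative to it, and counts are given as deposited and after median-of-ratios scaling.

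At 0 h the comparison addressed the earliest expression after cell death. The proapoptotic gene rpr (FBgn0011706, chromosome 3L, 18397535 to 18398435) stood at 11.4 FPKM in control and 108 FPKM in regenerating discs, a log2 ratio of 3.14. Apoptosis had been induced in the regenerating discs, and the labels do not describe their genotype. Whether the rpr reads came from the gene itself or from the induction therefore cannot be told. Gadd45 (FBgn0033153, chromosome 2R, 7249161 to 7250655), a stress-response gene, was higher at 14.4 and 49.9 FPKM in control and regenerating discs. Jra (FBgn0001291, chromosome 2R, 10096480 to 10098556), the fly Jun protein of the JNK pathway, stood at 27.4 and 63.8 FPKM. The glutathione transferase genes GstD10 (FBgn0042206, chromosome 3R, 12364776 to 12365735) and GstE3 (FBgn0063497, chromosome 2R, 18400713 to 18401467) were higher at 3.39 and 21.7 FPKM and 2.72 and 12.3 FPKM. The heat shock genes Hsp70Bbb (FBgn0051354, chromosome 3R, 12502510 to 12504856) and Hsp70Ab (FBgn0013276, chromosome 3R, 11958535 to 11960909) were lower at 36.5 and 3.65 FPKM and 164 and 57.6 FPKM. The Hsp70 genes are near-identical copies, so their separate values are uncertain.

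Among the lists fixed before the data were examined, 3 of 14 measured JNK pathway components were higher at 0 h and 0 lower. These were Jra, the TNF receptor gene wgn at 5.35 and 11.9 FPKM in control and regenerating discs, and Traf4 at 1.65 and 4.40 FPKM, although after median-of-ratios scaling 0 passed the rule. Of 12 measured genes reported as JNK targets, 3 were higher both as deposited and scaled. They were rpr, with the limit given above, Gadd45 and Ilp8, the last at 0 in control discs and only 1.55 FPKM in regenerating discs. The list median lay 0.19 above that of all measured genes, at percentile 95.36 of 10000 random lists matched on expression. Among genes above 0 in both columns 2 of 11 targets were higher, at percentile 90.85. At 15 h and 25 h the median of these targets lay at -0.16 and -0.18 relative to all genes, at percentiles 13.92 and 15.61. Of 18 measured Notch pathway genes and targets, 3 were higher. E(spl)m6-BFM stood at 34.9 and 111 FPKM in control and regenerating discs, E(spl)mdelta-HLH at 9.60 and 22.8 FPKM and E(spl)malpha-BFM at 177 and 369 FPKM. Their list was at percentile 98.8, and 1 member passed the rule after scaling. The proneural genes ac (FBgn0000022, chromosome X, 370031 to 370947) and sc, which start sensory organ formation, stood at 24.8 and 98.0 FPKM and 6.33 and 22.4 FPKM and passed the rule under both scalings.

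Of 27 measured oxidative stress and detoxification genes, 8 were higher as deposited, 5 after scaling, and 0 lower, while 19 lay within the rule and the list median was -0.02 relative to all genes, at percentile 52.48. Of 25 measured heat shock and unfolded protein response genes, 7 were lower and 1 was higher. The gene that was higher, Hsp83, stood at 205 and 531 FPKM and did not pass the rule after scaling. This list lay at percentile 0.66. The wing pouch patterning list had a median -0.38 relative to all genes, at percentile 0, with 1 of 13 members, sd, higher at 21 and 44.5 FPKM and 0 after scaling. The cell cycle and DNA replication list had a median 0.26 above all genes at percentile 100, with 1 of 32 members, the mitotic kinase gene aurA, past the rule at 13.9 and 38.0 FPKM and 0 after scaling. Of 18 Wingless pathway genes, sgg at 9.51 and 24.7 FPKM and wls at 18.4 and 40.8 FPKM were higher. Of 14 EGFR pathway genes, aos was higher at 3.49 and 8.79 FPKM, and of 16 Dpp pathway genes put was higher at 20.8 and 47.6 FPKM. None of sgg, wls, aos and put passed the rule after scaling.

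In all, 613 of 8202 measured genes were higher and 249 lower in regenerating discs at 0 h, a split of 71.1% higher. Median-of-ratios scaling, which moves every log2 ratio of well expressed genes down by 0.54, gave 195 higher and 450 lower, or 30.2% higher, and columns scaled to the same sum gave 739 and 161, or 82.1%. Of the 249 lower genes 178 were listed at 0 in regenerating discs, and genes above 0 in both columns gave 546 and 71. The 10 highest ratios among genes of at least 5 FPKM were led by CG18628, listed at 0 in control and at 101 FPKM in regenerating discs, 18SrRNA:CR41548, at 0 and 69.3 FPKM, and Reepl1, at 0 and 22.9 FPKM. The lowest were led by CG32640 at 117 and 4.36 FPKM, CG42500 at 96.1 and 4.51 FPKM and sncRNA:158, at 15.3 FPKM in control discs and 0 in regenerating discs.

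**Figure D1:**
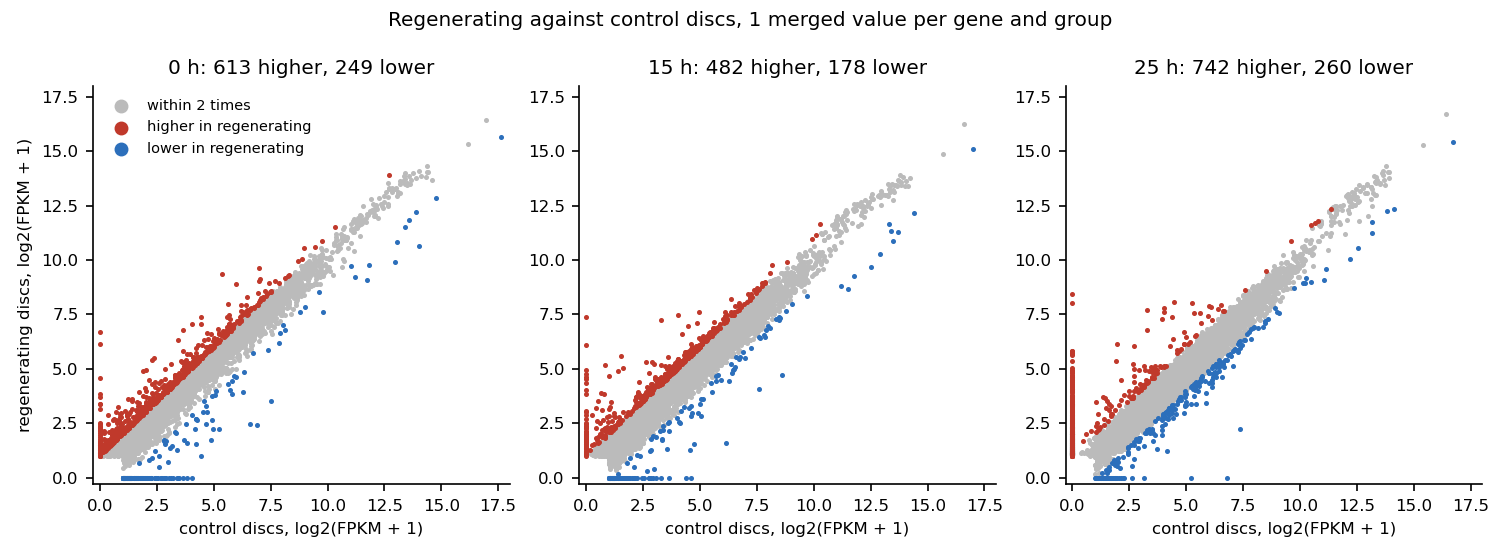
Each point is 1 gene, with log2(FPKM + 1) in control discs on the horizontal axis and in regenerating discs on the vertical axis, at 0 h, 15 h and 25 h. Red and blue points are genes higher and lower by the rule of 2 times, such as the 613 and 249 at 0 h, and the column of red points at 0 in the plot of 25 h holds 620 genes listed at 0 in control discs at 25 h.

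At 15 h genes of DNA replication and the cell cycle stood higher in regenerating discs. Of 32 measured members of that list, 9 were higher and 0 lower. The list median lay 0.42 above that of all measured genes, at percentile 100 of matched random lists. The replicative helicase gene dpa (FBgn0015929, chromosome 2R, 7496702 to 7500145) stood at 23.3 and 70.0 FPKM in control and regenerating discs. The kinase gene Cdk2 (FBgn0004107, chromosome 3R, 20735623 to 20738414) stood at 38.1 and 91.0 FPKM, the chromosomal passenger gene Incenp (FBgn0260991, chromosome 2R, 7278467 to 7281795) at 41.2 and 98.7 FPKM and the polymerase clamp PCNA (FBgn0005655, chromosome 2R, 20261754 to 20262883) at 229 and 496 FPKM. After median-of-ratios scaling only 1 of 32 members passed the rule, dpa with a scaled log2 ratio of 1.16. At 25 h 0 of 32 members were higher and 0 lower, 0 and 1 after scaling, and the list median lay 0.04 above that of all genes, at percentile 72.78.

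The secreted peptide gene Ilp8 (FBgn0036690, chromosome 3L, 17029812 to 17032080), which delays the onset of metamorphosis, was listed at 0 in control discs at 15 h and at 6.27 FPKM in regenerating discs. The growth regulator yki stood at 21.6 and 45.5 FPKM in control and regenerating discs, the Wingless receptor gene fz3 at 10.3 and 26.2 FPKM, and the notum genes eyg and toe at 4.07 and 9.61 FPKM and 3.51 and 9.97 FPKM. The Polycomb genes E(z) and esc were higher at 11.4 and 28.9 FPKM and 7.42 and 17.2 FPKM, while pho was lower at 236 and 111 FPKM, so that 2 of 24 chromatin regulators were higher and 1 lower. None of yki, fz3, eyg, toe, E(z) and esc passed the rule after scaling, and pho did. The TNF receptor gene grnd (FBgn0032682, chromosome 2L, 18485417 to 18488021) was lower under both, at 189 and 86.7 FPKM, whereas wgn stood at 8.27 and 16.4 FPKM.

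Of 24 heat shock and unfolded protein response genes, 5 were higher at 15 h and 1 lower. Hsp70Ab stood at 0.79 and 34.8 FPKM in control and regenerating discs and Hsp68 at 1.44 and 5.88 FPKM. Of 25 oxidative stress genes, 4 were higher, at percentile 98.91, and after scaling 1 was higher and 1 lower. Of 29 genes of glycolysis, mitochondrial and amino acid metabolism 5 were higher, at percentile 99.94. The latter included AsnS at 5.23 and 12.5 FPKM and Idh at 232 and 505 FPKM, and 0 passed after scaling. In the apoptosis list Dcp-1 was higher at 22.96 and 47.7 FPKM and Buffy was lower, at 1.27 FPKM in control discs and listed at 0 in regenerating discs, and Dcp-1 did not pass the rule after scaling. The wound response and extracellular matrix list lay at percentile 1.95, with hemocyte markers at percentile 1.58, although SPARC was higher at 45.9 and 115.3 FPKM. Markers of fat body, a different tissue, were also higher. Lsp2 stood at 0.725 and 13.3 FPKM and Obp99b at 1.92 and 47.5 FPKM.

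In all, 482 of 8095 measured genes were higher and 178 lower at 15 h, 73.0% higher. Scaling by median of ratios gave 131 and 329, or 28.5% higher, and scaling to the same sum gave 767 and 107, or 87.8%. Of the 178 lower genes 94 were listed at 0 in regenerating discs, and genes above 0 in both columns gave 430 and 84. The highest ratios were led by CG18628, at 0 in control and 167 FPKM in regenerating discs, 18SrRNA:CR41548, at 0 and 68.0 FPKM, and Mst57Db, at 0 and 29.7 FPKM. CG18628 and Mst57Db are short genes, at 10639740 to 10640136 on chromosome 3L and 25830720 to 25830914 on chromosome 3R. FPKM is scaled to length and read depth is unknown, so their values, also those of CG18628 at 0 h, may rest on few fragments. The lowest were led by sncRNA:158, at 23.7 FPKM in control discs and 0 in regenerating discs, Cyp4p2 at 70.5 and 1.98 FPKM, and 28SrRNA:CR45837, at 20.03 FPKM and 0.

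At 25 h, the last time, which was chosen to reach the restored pattern, single genes of several signalling pathways were lower in regenerating discs. The cell death gene hid (FBgn0003997, chromosome 3L, 18167745 to 18185641) stood at 15.5 and 4.45 FPKM in control and regenerating discs and the growth regulator Myc (FBgn0262656, chromosome X, 3373159 to 3391697) at 7.79 and 1.72 FPKM. The EGFR pathway genes sty (FBgn0014388, chromosome 3L, 3401153 to 3424935) and rho stood at 17.0 and 7.14 FPKM and 4.47 and 1.62 FPKM, and these 2 of 14 members were lower, with 0 higher. The proneural gene ac, higher at 0 h, stood at 71.2 and 23.9 FPKM, the TNF receptor gene grnd at 156 and 52.8 FPKM and the hinge gene Doc2 at 23.7 and 10.6 FPKM. Each of these genes also passed the rule after scaling. Ilp8 was listed at 0 in control discs and at 6.39 FPKM in regenerating discs.

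Several lists fixed beforehand lay low at 25 h by their medians relative to all measured genes, although few of their members passed the rule. These medians were -0.57 for wing pouch patterning (percentile 0.04), -0.45 for the EGFR pathway (percentile 0.38), -0.41 for the Dpp pathway (percentile 0.33) and -0.31 for the Notch pathway (percentile 1.15). At 0 h and 15 h the EGFR list had medians of 0.13 and -0.23 (percentiles 90.5 and 4.7). The Dpp list had -0.02 and -0.12 (percentiles 27.12 and 9.95) and the Notch list 0.20 and -0.18 (percentiles 98.8 and 8.11). Random lists were matched on expression and not on length. Across genes, ratios at 25 h ran against exonic length at a Spearman rho of -0.15. In the pouch list at 25 h vg stood at 26.1 and 19.1 FPKM in control and regenerating discs and bi at 9.38 and 4.76 FPKM, and 0 of 13 members were higher and 0 lower. In the Dpp list Mad stood at 31.2 and 17.1 FPKM. The Wingless, Hedgehog, hinge and notum, and ecdysone lists lay at percentiles 5.24, 5.33, 4.89 and 4.85. Cytosolic ribosomal protein genes lay at percentile 100, with a median 0.42 above all genes and 5 of 78 past the rule, 2 after scaling and 3 among genes above 0 in both columns.

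The genes that were higher at 25 h were mostly listed at 0 in control discs, so their lists depend on that column. Of 37 measured cuticle protein genes, 23 were higher, among them Lcp4 at 56.3 FPKM and Lcp1 at 27.6 FPKM in regenerating discs, both listed at 0 in control discs. Among the 17 above 0 in both columns, 3 were higher and 1 lower, and the median turned from 1.17 to -0.35. Of innate immune effector genes 4 were higher and 2 lower at 0 h, which scaling turned to 2 and 4, and 2 were higher at 15 h. At 25 h 9 of 15 were higher, against 2 of 8 above 0 in both columns. In the same comparison 7 of 9 markers of fat body, a tissue that makes many immune effectors, were higher, and 7 of 9 at 15 h. TotA stood at 21.1 FPKM and the antimicrobial peptide genes Drsl5 and Def at 23.8 FPKM and 8.76 FPKM in regenerating discs, all listed at 0 in control discs. PGRP-LC, a bacterial peptidoglycan receptor, was higher with both values above 0, at 1.16 and 6.64 FPKM. Of 27 oxidative stress genes, 8 were higher, against 1 of 20 above 0 in both columns. The heat shock list had 3 of 26 members higher and 4 lower at 25 h.

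In all, 742 of 8148 measured genes were higher and 260 lower at 25 h, and scaling gave 683 and 286. Of the 742, 620 were listed at 0 in control discs. Among the 7477 genes above 0 in both columns, a restriction chosen after the data were seen, 122 were higher and 209 lower, which turned the balance. The lowest ratios among these included Vps11 at 57.1 and 9.79 FPKM in control and regenerating discs, Ephrin at 42.5 and 9.37 FPKM, Nipped-B at 57.2 and 13.7 FPKM and Parp1 at 93.9 and 23.5 FPKM. The highest included Fbp1 at 2.85 and 69.3 FPKM and hpRNA:CR33940 at 15.1 and 218 FPKM.

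**Figure D2:**
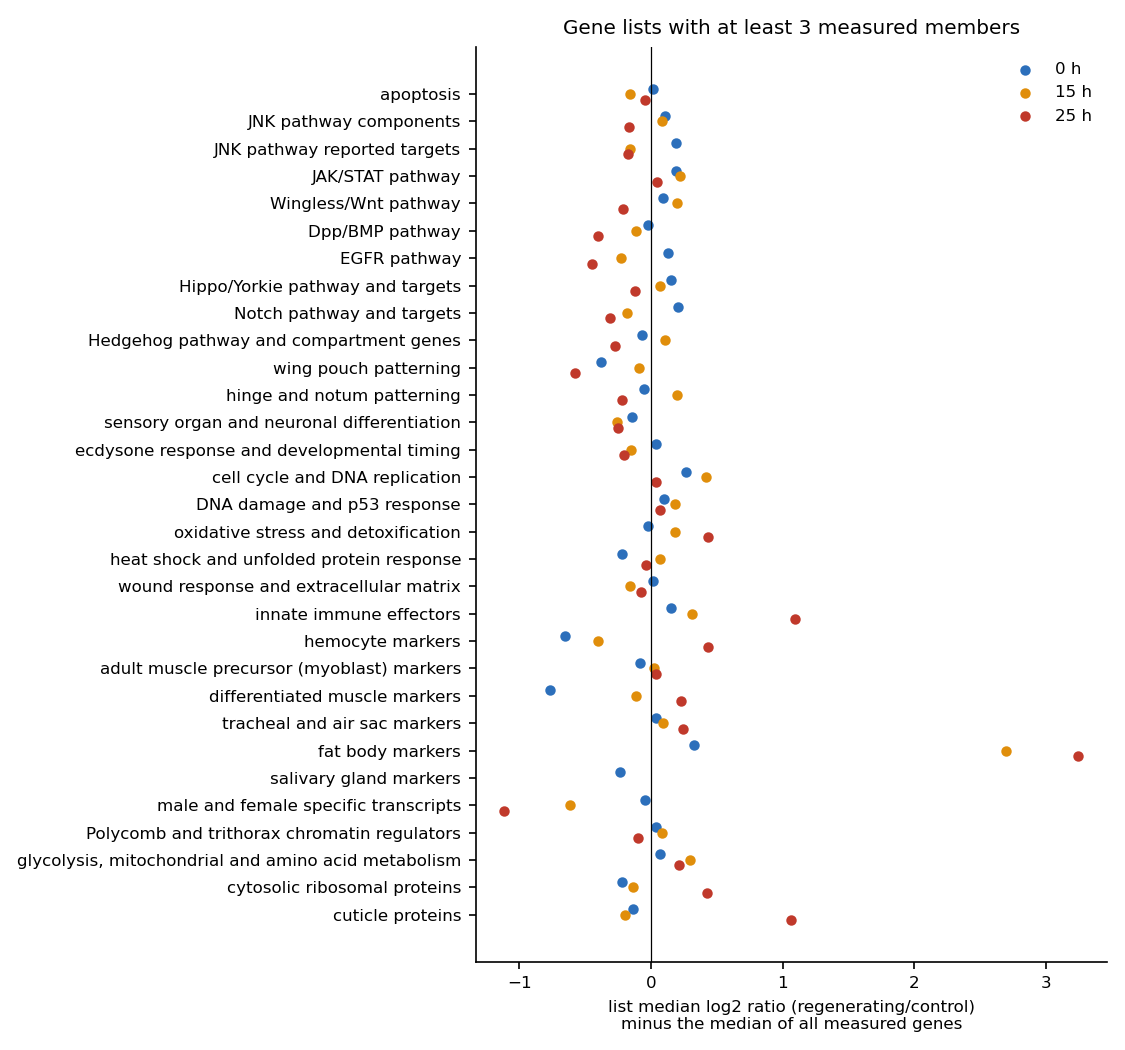
Each point is the median log2 ratio (regenerating over control) of the measured members of 1 fixed gene list, minus the median of all measured genes, with blue for 0 h, orange for 15 h and red for 25 h. Fat body markers lie farthest to the right, at 2.70 at 15 h and 3.24 at 25 h, and the red point of cuticle proteins at 1.06 rests on genes listed at 0 in control discs.

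Further lists had few members past the rule, and their medians are given relative to all measured genes at 0 h, 15 h and 25 h in turn. The apoptosis list had medians of 0.02, -0.16 and -0.05, with 2 of 11 members higher at 0 h, rpr among them, and 1 after scaling. JNK components had 0.10, 0.09 and -0.17, with grnd the 1 lower member at 15 h and at 25 h. Hippo pathway genes and targets had 0.16, 0.07 and -0.12, with sd higher at 0 h, yki at 15 h and Myc lower at 25 h. The DNA damage and p53 list had 0.10, 0.18 and 0.07, with the ribonucleotide reductase gene RnrS higher at 0 h at 72.3 and 152 FPKM in control and regenerating discs but not past the rule after scaling. The sensory organ list had -0.14, -0.26 and -0.25, the ecdysone list 0.03, -0.15 and -0.20, and the wound and matrix list 0.02, -0.16 and -0.08. In the wound list Ddc, an enzyme gene of cuticle hardening, stood at 0.54 and 5.53 FPKM at 0 h. Hedgehog pathway genes had -0.07, 0.11 and -0.27, hinge and notum genes -0.05, 0.20 and -0.22, and chromatin regulators 0.04, 0.08 and -0.10. Ribosomal protein genes had -0.22, -0.14 and 0.42, and metabolic genes 0.07, 0.30 and 0.21. Against random lists matched on expression, the ribosomal list lay at percentiles 36.27 at 0 h and 99.90 at 15 h. Its negative median at 15 h was therefore high for genes of such expression. Cuticle genes at 0 h were 8 higher and 6 lower of 35, turned by scaling to 7 and 9. At 15 h 4 were higher and 4 lower of 28, or 2 and 5 of 27 after scaling.

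Of the 10 genes fixed to be reported at every time, 9 were matched by symbol and wg is not analysed here. The JNK phosphatase gene puc (FBgn0243512, chromosome 3R, 8105332 to 8122294) stood at 4.55 and 8.56 FPKM in control and regenerating discs at 0 h, 6.49 and 8.55 FPKM at 15 h and 7.44 and 5.92 FPKM at 25 h, with no log2 ratio reaching 1. Mmp1 (FBgn0035049, chromosome 2R, 24671294 to 24688184), a matrix metalloproteinase gene, stood at 12.5 and 17.2, 20.6 and 17.3 and 15.0 and 16.6 FPKM at the 3 times in turn. The TNF ligand gene egr (FBgn0033483, chromosome 2R, 10078366 to 10084210) stood at 3.41 and 3.64, 2.48 and 4.36 and 2.52 and 4.88 FPKM, and Wnt6 (FBgn0031902, chromosome 2L, 7333714 to 7352542) at 9.32 and 12.2, 10.6 and 12.2 and 10.8 and 15.1 FPKM. Myc stood at 3.05 and 5.12, 9.87 and 14.8 and 7.79 and 1.72 FPKM. Ets21C and the cytokine gene upd3 were under 1 FPKM in every column, so neither was measured by the rule. The JAK/STAT list had 0 of 9 members past the rule at any time, although its receptor gene dome stood at 7.71 and 16.2 FPKM at 0 h and Socs36E at 7.62 and 16.1 FPKM, with list medians of 0.19, 0.22 and 0.05 relative to all genes.

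**Figure D3:**
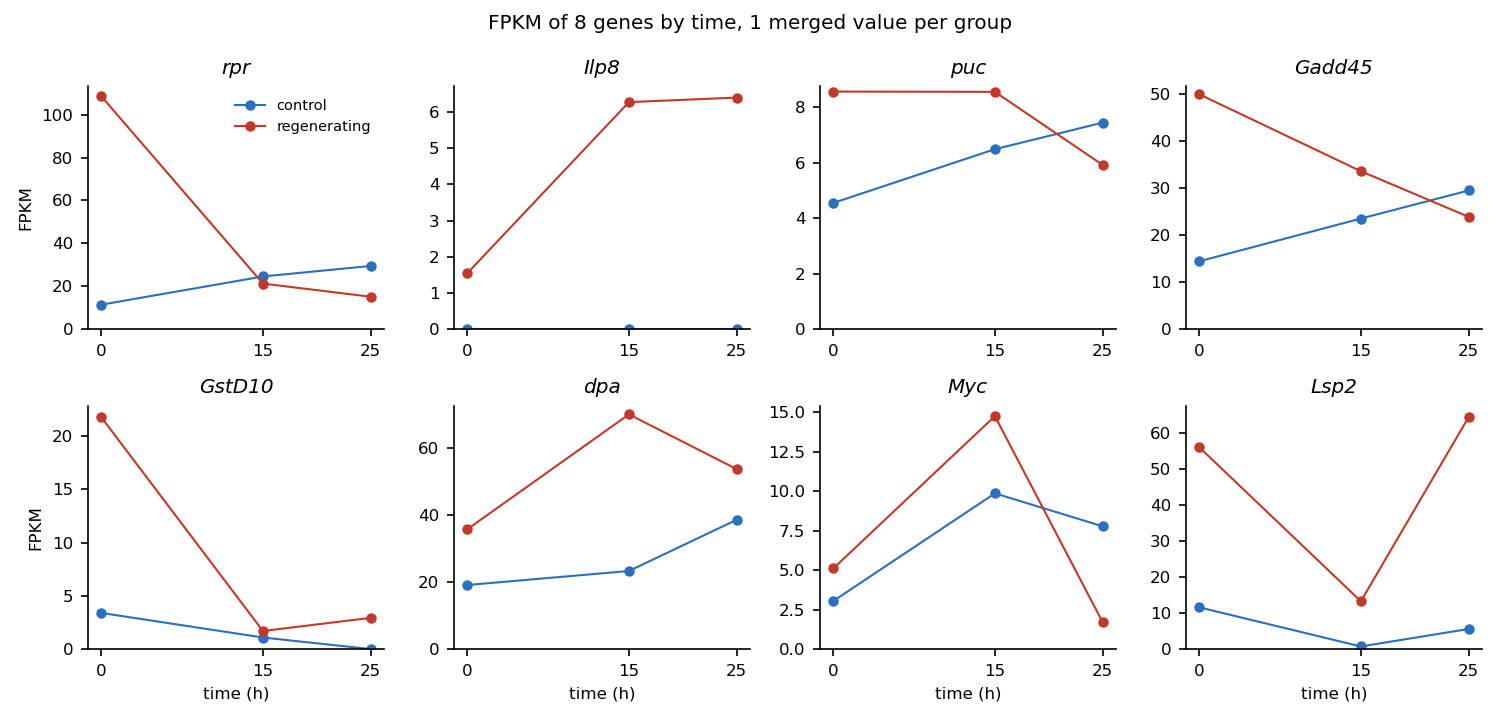
FPKM on the vertical axis against hours on the horizontal axis for 8 genes, with blue lines for control and red lines for regenerating discs, and each point 1 merged value with no error. The gene rpr reaches 108 FPKM in regenerating discs at 0 h and lies at 21.3 FPKM at 15 h, while Ilp8 is listed at 0 in all 3 control columns.

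The sets past the rule at different times overlapped more than independent sets of their size would, each time having its own control libraries. Of genes measured at both, 107 were higher at 0 h and at 15 h, against 29.9 for independent sets, and 79 were lower at both, against 2.74. At 15 h and 25 h 126 higher and 55 lower genes were shared, against 32.8 and 2.93. At 0 h and 25 h these numbers were 146 and 36, against 37.3 and 3.796. Among genes above 0 in both columns the shared numbers of higher and lower genes were 86 and 37 at 0 h and 15 h, 51 and 48 at 15 h and 25 h and 38 and 28 at 0 h and 25 h, and with median-of-ratios scaling 41 and 137, 79 and 98 and 90 and 51. By time, 422 genes were higher at 0 h without being higher at 15 h or 25 h, 311 at 15 h and 532 at 25 h. With median-of-ratios scaling these numbers were 98, 45 and 548, and among genes above 0 in both columns 448, 319 and 59, which turned the order of the times. For lower genes they were 166, 76 and 201 as deposited, 310, 142 and 185 scaled, and 32, 25 and 159 above 0 in both columns. Of genes in opposite directions, 29 were higher at 0 h and lower at 25 h, 8 with scaling and 29 among genes above 0 in both columns. In the other direction 82 were lower at 0 h and higher at 25 h, 102 with scaling and 2 among genes above 0 in both columns.

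At all 3 times, 62 genes were higher and 32 lower, and with median-of-ratios scaling 34 and 48. Among genes above 0 in both columns there were 26 and 26, or 12 and 43 with scaling as well. Reepl1 (FBgn0030313, chromosome X, 11572707 to 11573640) was listed at 0 in all 3 control columns and at 22.9, 22.1 and 31.5 FPKM in regenerating discs. The hairpin RNA locus hpRNA:CR33940 (FBgn0062928, chromosome 3L, 19486745 to 19488439) stood at 20.6 and 168 FPKM in control and regenerating discs at 0 h and the nearby entries hpRNA:CR32207 and CR42842, which overlap each other, at 20.5 and 131 FPKM and 15.3 and 132 FPKM. CG14715 stood at 9.71 and 77.9 FPKM at 0 h, and NijC at 3.09 and 14.9 FPKM. Among lower genes, CG32640 (FBgn0052640, chromosome X, 13178005 to 13178523) stood at 117 and 4.36 FPKM at 0 h, while CG32641, a gene of the same length nearby that was singled out after its values were seen, stood at 47.7 and 249 FPKM. Reads of such copies can be assigned to either, so the values of this pair are uncertain. Spn47C stood at 17.6 and 1.89 FPKM, Cyp4p2 at 54.3 and 13.4 FPKM and asRNA:CR45822 at 20.7 and 1 FPKM at 0 h. The amino acid synthesis gene AsnS and the collagen-binding matrix gene SPARC (FBgn0026562, chromosome 3R, 26869238 to 26871995) were higher at all 3 times, SPARC at 51.3 and 111, 45.9 and 115.3 and 49.6 and 135 FPKM. After scaling, AsnS passed the rule at 0 h and SPARC at 25 h.

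Transcripts encoded in the mitochondrial genome, a group added after the data were seen, were mostly lower in regenerating discs. Of 13 mRNAs, 9 were lower at 0 h, 10 at 15 h and 8 at 25 h, and 3, 1 and 3 were higher. After scaling the lower ones numbered 9, 10 and 8. The cytochrome oxidase gene mt:CoI stood at 12183 and 3723 FPKM in control and regenerating discs at 0 h, 13179.9 and 2520.0 FPKM at 15 h and 9152 and 2439 FPKM at 25 h. The gene mt:ND3 stood at 7989 and 960.5 FPKM at 0 h. Those that were higher at 1 or more times were the less abundant mt:ND6, mt:ND4L and mt:ATPase8. The first stood at 86.8 and 310.1 FPKM at 0 h and the last, which overlaps mt:ATPase6, at 61.6 and 469 FPKM. With the mitochondrial rRNAs included, this genome took 19.7%, 15.2% and 12.8% of FPKM in control discs at the 3 times, and 5.5%, 4.3% and 4.6% in regenerating discs. Most of that share was rRNA, since the mitochondrial rRNAs alone took 13.6%, 9.4% and 8.2% in control discs and 3.7%, 2.9% and 3.1% in regenerating discs. Nuclear rRNA took 0.0229%, 0.0463% and 0.0661% in control discs and 0.152%, 0.119% and 0.123% in regenerating discs. Nuclear genes of the respiratory chain, also a group added later, had medians of -0.15, 0.05 and 0.27 relative to all measured genes.

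**Figure D4:**
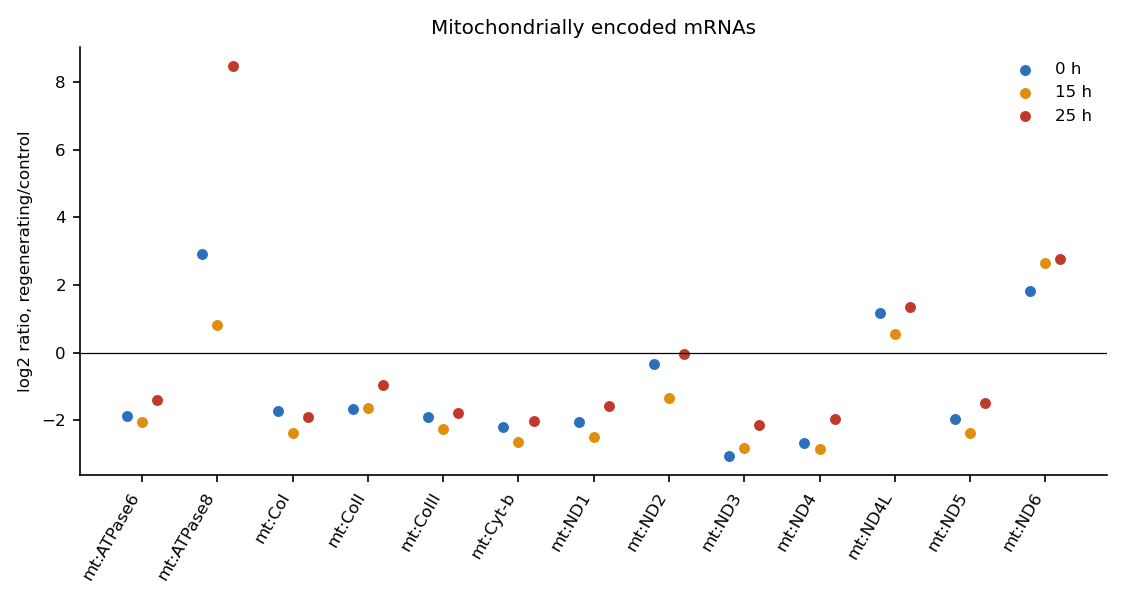
Log2 ratio of FPKM + 1, regenerating over control, on the vertical axis for each of the 13 mitochondrially encoded mRNAs on the horizontal axis, with blue, orange and red points for 0 h, 15 h and 25 h. Most points lie below 0, mt:ND3 lowest at -3.06 at 0 h, while mt:ND6 and mt:ND4L lie above 0 at every time, and the highest point, mt:ATPase8 at 25 h, rests on a control value of 0.

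Lists of other tissues described what else the discs' RNA held. Of 11 measured fat body markers, 5 were higher at 0 h, and 7 of 9 were higher at 15 h and 7 of 9 at 25 h, with 1 lower at 0 h and 0 later. After scaling 2 were higher and 2 lower at 0 h, and the later numbers were 7 and 7. The storage protein gene Lsp1beta (FBgn0002563, chromosome 2L, 898500 to 901316) stood at 17.6 and 51.5, 2.10 and 32.3 and 8.63 and 110.2 FPKM in control and regenerating discs at the 3 times. Fbp2 stood at 58.6 and 40.7, 1.61 and 28.4 and 14.4 and 156 FPKM. List medians relative to all genes were 0.33, 2.70 and 3.24. Hemocyte markers had 0 of 15 higher and 1 lower at 0 h, 0 of 13 higher at 15 h and 5 of 15 at 25 h, the last falling to 1 of 11 among genes above 0 in both columns. Their medians relative to all genes were -0.65, -0.40 and 0.43, at percentiles 0, 1.58 and 96.89. With a filter of 5 FPKM their median at 0 h, not taken relative to all genes, turned from -0.18 to 0.44. Of adult muscle precursor markers 2 of 10, 2 of 12 and 3 of 12 were higher in turn, and 0, 0 and 3 after scaling. These were SPARC, which the wound list also holds, and Ama at 0 h and 15 h, with SPARC, twi and Him at 25 h, twi at 7.33 and 17.9 FPKM and Him at 8.92 and 20.9 FPKM at 25 h. Differentiated muscle markers lay at percentile 0.01 at 0 h, with Mlc1 at 4.29 and 1.36 FPKM, and at 39.48 and 94.31 later. At 0 h 1 of 8 was lower, or 4 of 11 after scaling. With a filter of 5 FPKM their median at 0 h, not taken relative to all genes, turned from -0.30 to 0.23. None of 7 measured tracheal markers passed the rule at any time, at percentiles 55.87, 63.76 and 94.89. Of 8 measured salivary gland markers, 1 was higher and 2 lower at 0 h, with Sgs8 at 9.76 FPKM in control discs and listed at 0 in regenerating discs, and 2 and 1 were measured later.

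The list of male and female specific transcripts holds lncRNA:roX2 (FBgn0019660, chromosome X, 11579065 to 11580432), an RNA of male dosage compensation. It was lower at all 3 times, at 282 and 111, 44.7 and 14.1 and 39.1 and 12.4 FPKM. The female sex determination gene Sxl stood at 36.8 and 60.7, 99.6 and 68.1 and 77.8 and 27.3 FPKM. FPKM per gene does not tell splice forms apart, so the Sxl values do not measure RNA of females. Of 6 measured members, 3 were lower at 25 h, with list medians relative to all genes of -0.05, -0.61 and -1.11 at the 3 times. The sex of the larvae was not given in the labels. The accessory gland genes Mst57Db and Met75Cb were above 0 only in regenerating discs at 15 h, at 29.7 and 23.4 FPKM. Both are short genes, so these values may rest on few fragments.

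Within control discs, 406 genes were higher and 169 lower at 15 h than at 0 h of 8072 measured, with median-of-ratios scaling 137 and 359 and with columns scaled to the same sum 531 and 109. Genes above 0 in both columns gave 377 and 92. The cuticle gene Cpr78E stood at 25.6 FPKM at 0 h and 141 FPKM at 15 h, CG10581 at 6.25 and 73.3 FPKM, and the immune receptor gene PGRP-SA at 1.69 and 18.7 FPKM. Hsp70Ab stood at 164 and 0.79 FPKM. From 15 h to 25 h, 80 genes were higher and 421 lower, of which 412 were listed at 0 at 25 h, so that among genes above 0 in both columns 25 were higher and 9 lower. Median-of-ratios scaling gave 68 and 476, and 16 and 25 among genes above 0 in both columns, which turned that balance. At 25 h against 0 h the numbers were 542 and 517, or 85 and 925 after median-of-ratios scaling and 1001 and 330 after scaling to the same sum. Of the 517 lower genes 475 were listed at 0 at 25 h, and genes above 0 in both columns gave 503 and 42. Hsp83 stood at 205 FPKM at 0 h and 1083 FPKM at 25 h.

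Within regenerating discs, 267 genes were higher and 302 lower at 15 h than at 0 h, with median-of-ratios scaling 159 and 386 and with the same sum 332 and 193, and among genes above 0 in both columns 133 and 161. Of these, rpr stood at 108 FPKM at 0 h and 21.3 FPKM at 15 h, GstD10 at 21.7 and 1.70 FPKM, and betaTub97EF at 5.31 and 54.6 FPKM. From 15 h to 25 h 234 were higher and 211 lower, with these scalings 250 and 129, or 182 and 300, and above 0 in both columns 93 and 165. Myc stood at 14.8 FPKM at 15 h and 1.72 FPKM at 25 h, Ephrin at 38.9 and 9.37 FPKM, and Lcp4 at 3.27 and 56.3 FPKM. At 25 h against 0 h 375 were higher and 315 lower, with scaling 318 and 358, and above 0 in both columns 163 and 227. Across genes, which are not independent replicates, the change from 0 h to 15 h ran with exonic length, at a Spearman rho of 0.45 in control and 0.41 in regenerating discs. From 15 h to 25 h rho was -0.08 and -0.33, and from 0 h to 25 h 0.39 and 0.10, in control and regenerating discs in turn, against 0.10, 0.07 and -0.15 for regenerating over control at 0 h, 15 h and 25 h.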

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

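The tests in this part on fat body and mitochondrial transcripts were chosen only after those results had been seen. The differences between times given next were picked because a gene was past the rule of 2 times in opposite directions at 2 times, and they were not tested, since each group has 1 merged value.

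Between 0 h and 25 h, the log2 ratio of the proneural gene ac moved from 1.94 to -1.54, a difference of -3.47, and that of Ephrin, a ligand of the Eph receptor, from 1.40 to -2.07, also -3.47. Nipped-B, which loads cohesin onto chromosomes, went from 1.04 to -1.98 (-3.02), CG15212 from 1.81 to -1.08 (-2.89) and CG45086 from 1.09 to -1.01 (-2.10). After median-of-ratios scaling Ephrin, Nipped-B and CG45086 did not pass the rule at 0 h, at 0.90, 0.53 and 0.88. Some heat shock genes, with 3 of 26 members of their list higher and 4 lower at 25 h, went the other way, whereas Hsp83 went from 1.36 to -0.17. Hsp70Ab stood at -1.49 at 0 h, 4.32 at 15 h and 1.78 at 25 h, differences from 0 h of 5.81 and 3.27. Hsp70Bb moved from -1.31 at 0 h to 1.89 at 15 h (3.20), Hsp70Bbb from -3.01 at 0 h to 1.28 at 25 h (4.29) and Hsp68, at -1.11 at 0 h, was 2.61 above that at 15 h. The Hsp70 genes are near-identical copies, so their separate values are uncertain. CG42500 moved from -4.14 at 0 h to 2.19 at 15 h (6.33) and CG34227 from -3.15 to 1.40 (4.55). These 2 moves lay mostly in control discs. CG42500 stood there at 96.1 and 1.07 FPKM, against 4.515 and 8.465 FPKM in regenerating discs, and CG34227 at 28.1 and 0.54 against 2.28 and 3.06 FPKM. From 0 h to 15 h Hsp70Ab went from 164 to 0.79 FPKM in control and 57.6 to 34.8 FPKM in regenerating discs. Every difference from 0 h rests in part on the control column at 0 h, whose origin is unclear. The antisense RNA asRNA:CR44031 stood at 1.11 at 15 h and -1.34 at 25 h (-2.45), with 0.75 at 15 h after scaling, and whether its reads were told apart by strand is not given in the sources used here.

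Fat body transcripts, such as Lsp2 and Fbp2, were higher in regenerating discs at 15 h and 25 h. A difference in scaling does not account for this, since the lower of the 2 list medians after median-of-ratios scaling was 2.73. Fat body adhering to the discs may have carried them in, which would move all members together over the 6 columns. Over the 8 list members measured at every time, including the abundant Obp99b at 267 FPKM in regenerating discs at 25 h, the residual SD was 0.512 of the SD of the column means. A first version of this test on 7 chosen transcripts gave 0.344. It left out Mtp, which varied little, from 7.09 to 12.84 FPKM over the 6 columns. The value of 0.344 is close to the bound below which the members would count as moving together. Both values lie between the bounds set, so adhering tissue and expression in the discs cannot be told apart here.

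Most mitochondrially encoded mRNAs were lower in regenerating discs at every time. Scaling does not account for this, since at least 8 of the 13 stayed lower by the rule at each time after median-of-ratios scaling, a count that replaced a first test on set medians with an upper bound of -0.08 at 25 h. Fewer mitochondria might also lower nuclear respiratory chain genes, whose scaled medians were -0.21 at 0 h, 0.00 at 15 h and 0.33 at 25 h. Resampling intervals over genes, which do not measure spread between discs, were -0.30 to -0.11, -0.15 to 0.17 and 0.18 to 0.43. The last 2 intervals lie above the bound of -0.25 and argue against fewer mitochondria at 15 h and 25 h, as far as these genes follow their number, while the interval at 0 h spans it. The rise at 25 h is not particular to these genes, since ribosomal protein genes had a scaled median of 0.47 at that time. A difference in how RNA without long poly(A) tails entered the libraries could lower nuclear rRNA, snRNA, snoRNA and 7SL genes as well. Their scaled medians were 1.82, 0.41 and 0.68, the opposite direction. These rest on 8 to 11 genes with intervals that all reach below 0, such as -1.42 to 1.17 at 15 h, which leaves such a difference open. Mitochondrial rRNAs took 13.6% of FPKM in control and 3.7% in regenerating discs at 0 h. They belong to the same genome as the mRNAs, so this does not tell the explanations apart.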

How the results depend on the processing

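The alternatives to genes above 0 in both columns, no restored decimal point and nuclear protein-coding genes were chosen only after the data had been seen, and the others were fixed beforehand. Without replicates, a list median or gene counted as moved when it shifted by over 0.5 on the log2 scale or crossed the rule of 2 times, and a count of genes when it shifted by over 1.5 times. No paired analysis was possible because each column merges its replicates, and leaving out each replicate and the fit with a replicate block were not run for the same reason. List medians here are not taken relative to all genes. Leaving out the filter on low values cannot alter a count of genes, since with a pseudocount of 1 the rule of 2 times already needs 1 FPKM in 1 or both columns. With columns scaled to a sum of 1000000, all 91 list medians did not move. That was largely fixed beforehand, since column sums of 1247527 to 1504200 differ too little to shift ratios of well expressed genes by 0.5. Under median-of-ratios scaling 80 of 91 list medians and 445 of 578 values of named genes did not move. Its shifts of 0.54, 0.40 and 0.05 at 0 h, 15 h and 25 h exceed 0.5 only at 0 h. At the later times a list median could therefore hardly move other than by crossing the rule. Of list medians past the rule, 1 turned its direction, that of cuticle proteins at 25 h. Smaller list medians also changed sign under median-of-ratios scaling, such as that of apoptosis at 0 h. Beyond the construction of each alternative, such as fewer genes or a stricter rule, the cause was not tested. Depth is unknown, so what it limits could not be given.

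With a pseudocount of 0.1, regenerating against control discs gave 970 higher at 0 h and 728 higher at 15 h. For control discs a pseudocount of 0.1 gave 757 higher and 263 lower for 15 h over 0 h and 934 higher for 25 h over 0 h. Shared genes with a pseudocount of 0.1 were 102 higher at all 3 times, 182 higher at 0 h and 15 h and 216 higher at 15 h and 25 h. List medians under a pseudocount of 0.1 were 2.42 for innate immune effectors at 25 h, 4.02 for fat body markers at 15 h and 3.58 for cuticle proteins at 25 h.

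With a pseudocount of 5, regenerating against control discs gave 186 higher and 66 lower at 0 h, 191 higher and 66 lower at 15 h and 186 higher and 121 lower at 25 h. For control discs a pseudocount of 5 gave 119 higher and 53 lower for 15 h over 0 h, 17 higher and 51 lower for 25 h over 15 h and 180 higher and 91 lower for 25 h over 0 h. Between times a pseudocount of 5 gave 61 higher and 68 lower for 15 h over 0 h, 67 higher and 76 lower for 25 h over 15 h and 92 higher and 134 lower for 25 h over 0 h in regenerating discs. Shared genes with a pseudocount of 5 were 24 higher at all 3 times, 36 higher and 36 lower at 0 h and 15 h, 41 higher and 35 lower at 15 h and 25 h and 32 higher at 0 h and 25 h. List medians under a pseudocount of 5 were 0.39 for innate immune effectors at 25 h, 1.68 for fat body markers at 15 h, 2.71 for fat body markers at 25 h, -0.87 for male and female specific transcripts at 25 h and 0.46 for cuticle proteins at 25 h.

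List medians under no filter on low values were 0.00 for innate immune effectors at 0 h, 0.00 for innate immune effectors at 15 h, 0.00 for innate immune effectors at 25 h, 0.42 for fat body markers at 15 h, 0.83 for fat body markers at 25 h, -0.44 for male and female specific transcripts at 25 h and 0.00 for cuticle proteins at 25 h.

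With an FPKM of at least 5, regenerating against control discs gave 81 lower at 0 h, 87 lower at 15 h and 234 higher at 25 h. For control discs an FPKM of at least 5 gave 73 lower for 15 h over 0 h, 25 higher and 54 lower for 25 h over 15 h and 101 lower for 25 h over 0 h. Between times an FPKM of at least 5 gave 135 higher and 139 lower for 15 h over 0 h, 91 higher for 25 h over 15 h and 160 higher for 25 h over 0 h in regenerating discs. Shared genes with an FPKM of at least 5 were 37 higher at all 3 times, 42 lower at 0 h and 15 h, 66 higher at 15 h and 25 h and 64 higher at 0 h and 25 h. List medians under an FPKM of at least 5 were 0.56 for innate immune effectors at 25 h, 0.44 for hemocyte markers at 0 h and 0.23 for differentiated muscle markers at 0 h.

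With median-of-ratios scaling, regenerating against control discs gave 195 higher and 450 lower at 0 h and 131 higher and 329 lower at 15 h. For control discs median-of-ratios scaling gave 137 higher and 359 lower for 15 h over 0 h and 85 higher and 925 lower for 25 h over 0 h. Between times median-of-ratios scaling gave 159 higher for 15 h over 0 h and 129 lower for 25 h over 15 h in regenerating discs. Shared genes with median-of-ratios scaling were 34 higher at all 3 times, 41 higher and 137 lower at 0 h and 15 h, 79 higher and 98 lower at 15 h and 25 h and 90 higher at 0 h and 25 h. List medians under median-of-ratios scaling were -0.03 for apoptosis at 0 h, 0.07 for JNK pathway components at 0 h, 0.16 for Notch pathway and targets at 0 h, 0.23 for cell cycle and DNA replication at 0 h, -0.28 for heat shock and unfolded protein response at 0 h, -0.02 for tracheal and air sac markers at 0 h, 0.14 for fat body markers at 0 h, -0.08 for male and female specific transcripts at 0 h, 0.02 for glycolysis, mitochondrial and amino acid metabolism at 0 h, -0.29 for cytosolic ribosomal proteins at 0 h and -0.20 for cuticle proteins at 0 h.

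With columns scaled to a sum of 1000000, regenerating against control discs gave 161 lower at 0 h and 767 higher and 107 lower at 15 h. For control discs columns scaled to a sum of 1000000 gave 109 lower for 15 h over 0 h, 273 lower for 25 h over 15 h and 1001 higher and 330 lower for 25 h over 0 h. Between times columns scaled to a sum of 1000000 gave 193 lower for 15 h over 0 h in regenerating discs. Shared genes with columns scaled to a sum of 1000000 were 50 lower at 0 h and 15 h.

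With a rule of 1.5 times, regenerating against control discs gave 2928 higher at 0 h, 2379 higher and 393 lower at 15 h and 1213 higher and 793 lower at 25 h. For control discs a rule of 1.5 times gave 2019 higher and 385 lower for 15 h over 0 h, 363 higher for 25 h over 15 h and 3140 higher for 25 h over 0 h. Between times a rule of 1.5 times gave 1311 higher and 644 lower for 15 h over 0 h, 411 higher and 913 lower for 25 h over 15 h and 961 higher and 888 lower for 25 h over 0 h in regenerating discs. Shared genes with a rule of 1.5 times were 202 higher and 61 lower at all 3 times, 1050 higher and 131 lower at 0 h and 15 h, 503 higher and 169 lower at 15 h and 25 h and 355 higher and 68 lower at 0 h and 25 h.

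With a rule of 4 times, regenerating against control discs gave 50 higher and 55 lower at 0 h, 50 higher and 34 lower at 15 h and 237 higher and 16 lower at 25 h. For control discs a rule of 4 times gave 12 higher and 51 lower for 15 h over 0 h, 22 higher and 99 lower for 25 h over 15 h and 15 higher and 146 lower for 25 h over 0 h. Between times a rule of 4 times gave 39 higher and 47 lower for 15 h over 0 h, 58 higher and 18 lower for 25 h over 15 h and 75 higher and 43 lower for 25 h over 0 h in regenerating discs. Shared genes with a rule of 4 times were 13 higher and 6 lower at all 3 times, 17 higher and 17 lower at 0 h and 15 h, 34 higher and 8 lower at 15 h and 25 h and 20 higher and 7 lower at 0 h and 25 h.

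With genes above 0 in both columns, regenerating against control discs gave 71 lower at 0 h, 84 lower at 15 h and 122 higher at 25 h. For control discs genes above 0 in both columns gave 92 lower for 15 h over 0 h, 25 higher and 9 lower for 25 h over 15 h and 42 lower for 25 h over 0 h. Between times genes above 0 in both columns gave 133 higher and 161 lower for 15 h over 0 h, 93 higher for 25 h over 15 h and 163 higher for 25 h over 0 h in regenerating discs. Shared genes with genes above 0 in both columns were 26 higher at all 3 times, 37 lower at 0 h and 15 h, 51 higher at 15 h and 25 h and 38 higher at 0 h and 25 h. List medians under genes above 0 in both columns were 0.36 for innate immune effectors at 25 h and -0.35 for cuticle proteins at 25 h.

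With genes above 0 in both columns and median-of-ratios scaling together, regenerating against control discs gave 135 higher at 0 h, 85 higher at 15 h and 106 higher at 25 h. For control discs genes above 0 in both columns and median-of-ratios scaling together gave 103 higher for 15 h over 0 h, 16 higher and 25 lower for 25 h over 15 h and 49 higher and 304 lower for 25 h over 0 h. Between times genes above 0 in both columns and median-of-ratios scaling together gave 52 higher for 15 h over 0 h, 118 higher and 91 lower for 25 h over 15 h and 123 higher for 25 h over 0 h in regenerating discs. Shared genes with genes above 0 in both columns and median-of-ratios scaling together were 12 higher at all 3 times, 25 higher at 0 h and 15 h, 24 higher and 92 lower at 15 h and 25 h and 17 higher at 0 h and 25 h.

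With genes with no restored decimal point, regenerating against control discs gave 290 higher at 0 h, 159 higher and 68 lower at 15 h and 342 higher and 96 lower at 25 h. For control discs genes with no restored decimal point gave 205 higher for 15 h over 0 h, 41 higher and 220 lower for 25 h over 15 h and 270 higher for 25 h over 0 h. Between times genes with no restored decimal point gave 109 higher and 105 lower for 15 h over 0 h, 95 higher and 80 lower for 25 h over 15 h and 148 higher and 98 lower for 25 h over 0 h in regenerating discs. Shared genes with genes with no restored decimal point were 7 higher and 2 lower at all 3 times, 22 higher and 29 lower at 0 h and 15 h, 22 higher and 5 lower at 15 h and 25 h and 28 higher and 14 lower at 0 h and 25 h. List medians under genes with no restored decimal point were 1.12 for oxidative stress and detoxification at 25 h, 1.27 for innate immune effectors at 15 h, -0.86 for differentiated muscle markers at 0 h, 0.20 for fat body markers at 0 h, 0.83 for fat body markers at 25 h and -0.96 for salivary gland markers at 0 h.

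With nuclear protein-coding genes, regenerating against control discs gave 148 lower at 0 h and 90 lower at 15 h. For control discs nuclear protein-coding genes gave 259 lower for 25 h over 15 h. Shared genes with nuclear protein-coding genes were 33 higher and 17 lower at all 3 times, 70 higher and 37 lower at 0 h and 15 h, 35 lower at 15 h and 25 h and 94 higher and 19 lower at 0 h and 25 h.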

Other observations

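The tests on genes past the rule at all 3 times were chosen only after that result had been seen, and the tests on delay and transcript length were set before theirs had been computed.

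The nuclear rRNA, snRNA, snoRNA and 7SL genes, a group added later, had medians 1.61, 0.45 and 0.63 above all measured genes at 0 h, 15 h and 25 h, with 7 of 11, 3 of 8 and 2 of 8 members higher. In turn 0, 2 and 1 were lower, and after scaling 2 were higher and 2 lower at 15 h. At 0 h 28SrRNA:CR45837 stood at 39.5 and 653 FPKM in control and regenerating discs, while at 15 h it was listed at 20.03 FPKM and 0. Among genes above 0 in both columns the median at 0 h turned to -0.29. Sgs8, a salivary glue gene, was listed at 9.76 FPKM in control discs at 0 h and at 0 in regenerating discs. Tubulin gene betaTub97EF stood at 5.31 FPKM at 0 h and 59.7 FPKM at 25 h in regenerating discs, and Porin2, a mitochondrial porin gene, at 7.195 and 0.575 FPKM at 0 h and 15 h.

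One hypothesis is that regenerating discs at 25 h lag behind control discs in development. Across 7453 genes above 0 in the 4 columns, the log2 ratio of regenerating over control discs at 25 h ran against the change of control discs from 0 h to 15 h, with no column in common, at a Pearson r of -0.427 and a Spearman rho of -0.462. Transcript length and gene span, which also go with the change of control discs, do not account for it alone, since r was -0.404 with both taken out over 7300 genes and -0.433 before. At 15 h the same test against the change of control discs from 0 h to 25 h gave an r of 0.204 over 7455 genes, which argues against such a lag at that time. Computed in addition at 0 h, against the change from 15 h to 25 h, r was 0.202 and rho 0.205. That control change lies after 0 h and was small, with 25 genes higher and 9 lower among those above 0 in both columns. It therefore cannot decide on a lag at 0 h. At 25 h the values went with a lag and at 15 h they did not. Genes are not independent replicates and each group is 1 merged value, so a difference in the staging of 1 group may give the same values.

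Another hypothesis is that some genes past the rule at all 3 times differ between the genotypes of the discs rather than with regeneration. Of 77 such genes on the main chromosomes, 29 had another of them within 100 kb, with neighbours whose symbols share a stem counted once. In 10000 random draws the median was 12 and the 95th percentile 20. Without merging by symbol the number was 31, equal to the highest of the random draws. Copies in tandem whose symbols share no stem were not merged, so the 29 may still hold such families. Entries that overlap were among those with a neighbour, such as asRNA:CR44850 within l(2)34Fc, and hpRNA:CR32207 with CR42842. Reads shared by such entries may also raise the number, and the random draws do not allow for this. Reepl1 and lncRNA:roX2 are both on chromosome X, at 11572707 and 11579065. The number of neighbours may reflect differences in genetic background, shared reads or families in tandem, which were not told apart. Genotype and regeneration were the same split of the libraries, so a response of neighbouring genes to regeneration cannot be excluded either.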
